A study of Mus musculus with 9 samples.

How the data were processed

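The authors deposited 1 table of counts per library, in which each value is a whole number of reads per Ensembl gene with no normalization. According to the submitters' notes, TruSeq stranded libraries of total RNA were read as single ends of 50 bases, aligned with STAR 2.4.0j, handled with Picard and counted with featureCounts of the Subread package. Per the file headers, the counted alignments had duplicate reads removed. Removing duplicates limits how many reads a highly expressed gene can hold: between 7 and 121 genes per library exceeded 0.5 reads per exon base, the highest value was 0.944, and 0 genes exceeded 1. The genome build and the annotation used for counting were not given in the sources used here. Positions, gene types, symbols and exon GC content came from GENCODE M21 on GRCm38, matched by gene ID, which covered 32937 of the 37990 genes and 99.351 to 99.464% of the reads of each library. The 3 libraries whose titles name neither Fam60a nor Sin3a were taken as the scrambled hairpin controls by elimination.

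Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the 3 groups, libraries were scaled by TMM, and all 9 libraries were fitted in 1 model of 3 groups with robust quasi-likelihood F-tests. Calls used a Benjamini-Hochberg adjusted p under 0.05 over 14465 genes, and every p given for a gene comes from this edgeR fit unless another tool is named. The biological coefficient of variation was 0.25. Fold changes of genes are the log2 coefficients of this fit, with an SE derived from the fold change and its F statistic. A prior count of 2 was used for log CPM values, from which library deviations, differences within pairs and the covariance were taken. CPM values are TMM-scaled means with the SD of 3 libraries. Where a group held 1 to 3 reads of a gene, the ratio of reads per total is given with an exact binomial (Clopper-Pearson) interval of 95%, and where it held 0, a lower bound against 3 counts over the group. Under each scaling the median log2 fold change of all genes lay within 0.056 of 0. Each scaling centres the bulk of genes, so this median cannot show whether all transcripts changed together.

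The replicate numbers paired the samples. Deviations from the group means correlated between same-numbered libraries of different groups with r of 0.178 to 0.622 in 9 of 9 pairs, against -0.448 to 0.113 between libraries of different numbers, across genes, which are not independent replicates. Deviations within a group cancel by construction, so higher values for the same number force lower ones for different numbers. All 9 libraries correlated best with their own number in each other group. The labels do not say that same-numbered libraries were handled together, and the model without a replicate block had been fixed, so the fit with the replicate number as a block is given beside each count of genes and beside each call described that it changes.

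The named genes were chosen by a rule. It takes Fam60a and Sin3a, and for each knockdown the 12 largest rises and 12 largest falls among called protein-coding genes with a mean of at least 2 CPM over the 6 libraries, no overlap of libraries and a symbol that is not a clone name. It also takes up to 3 risen and 3 fallen members of each list with the smallest adjusted p, and a fixed set of Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Cdkn1a, Cdkn1c, Hdac1, Hdac2, Sin3b and Tet1. Among genes called in both knockdowns it takes the 5 per direction with the largest smaller change and 5 per opposite pattern, and between the knockdowns the 8 per direction with the largest change. The model, the filter, the thresholds, this rule, the alternatives not described as added and the 30 gene lists were chosen before the data were examined.

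The lists were SIN3-HDAC complex subunits, general, naive and primed pluripotency, primitive endoderm, primitive streak and mesendoderm, trophectoderm and neuroectoderm. Others were smooth muscle with actin and SRF targets, Hox cluster genes, germline and meiosis, two-cell-like state, p53 targets, CDK inhibitors and RB family, G1/S and DNA replication, G2/M and mitosis, and Myc and ribosome biogenesis. The rest were glycolysis and hypoxia response, cholesterol biosynthesis, oxidative phosphorylation, integrated stress response, interferon response, TGF-beta and BMP response, DNA methylation enzymes, imprinted genes, Polycomb subunits, fibroblast markers, immediate early and heat shock genes, replication-dependent histones, and mitochondrially encoded genes. No gene was found for 17 list entries. The entry Tcf3, an older name of Tcf7l1, matched both Tcf7l1 and the gene now named Tcf3, and both were counted. Lists with at least 5 tested genes, which all 30 had, were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Of 16 list calls, 0 held with an estimated correlation. The median, the mean and the test differed in sign for 5 lists in the Fam60a comparison, 8 in the Sin3a comparison and 4 between the knockdowns, of which 0 were called.

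Alternatives were DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors in edgeR, no filter or a mean of at least 1 CPM, and the replicate block. Others were each contrast on its own 6 libraries, a minimum log2 fold change of 1, an adjusted p under 0.01, each library left out in turn, and camera with an estimated correlation or fry for lists. A GC correction, the replicate block with that correction, and the replicate block without Sin3a knockdown replicate 3 were added after seeing the data. The correction removed from each library a loess trend (span 0.4) over exon GC content through the offsets, for the 14126 genes with a known content. The pipeline was tested on simulated data with changed genes. It called 63.6 to 78.8% of genes changed 4-fold, 25.4 to 28.4% of those changed 2-fold and 1.49 to 4.48% of those changed 1.5-fold, with 3 to 7 false calls among 69 to 77. A list shifted in the simulation was called and 0 other lists were. The simulated genes varied independently of each other, so this cannot show how the list test behaves when members vary together. In a simulated library with a GC trend the correlation with GC content went from 0.85 to 0.0182 after correction.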

Results

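The series measured transcripts by sequencing total RNA from mouse E14 embryonic stem cells, a line kept undifferentiated with leukaemia inhibitory factor and serum. The cells carried a stable lentiviral short hairpin RNA against Fam60a, against Sin3a, or with no target in the mouse genome, with 3 libraries in each of the 3 groups. Sin3a is the scaffold of a histone deacetylase corepressor complex and Fam60a is one of its subunits, named Sinhcaf in the GENCODE M21 annotation. Total counts were 6475568, 7674887 and 6344213 reads in the Fam60a knockdown, 6560637, 5511453 and 2607872 in the Sin3a knockdown, and 6072157, 6896141 and 6631622 in the controls. A floor of 3 counts corresponded to between 0.391 and 1.15 CPM (reads of a gene scaled to library size) in these libraries. Floors and counting intervals cover counting error only, since they leave out the spread between replicates. Duplicate reads had been removed, but without molecular tags reads need not be independent molecules. Of 37990 genes listed, 14465 passed the filter on low counts and were tested.

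The first comparison asked whether each hairpin lowered its own target. Fam60a transcripts (Sinhcaf, ENSMUSG00000039985, GRCm38 chromosome 6, 148921035 to 148946467, minus strand) stood at 13.5 ± 0.47 CPM in the controls and 5.73 ± 0.75 CPM in the Fam60a knockdown (SD, n = 3 each), which was 42.5% of control. The fall was -1.23 ± 0.23 on the log2 scale (SE, adjusted p = 0.028), from 32 to 51 reads per knockdown library and 82 to 97 per control library. Sin3a transcripts (ENSMUSG00000042557, GRCm38 chromosome 9, 57072040 to 57128366, plus strand) stood at 287 ± 21.9 CPM in the controls and 126 ± 13.4 CPM in the Sin3a knockdown (SD, n = 3 each), which was 43.8% of control. That fall was -1.19 ± 0.11 on the log2 scale (SE, adjusted p = 0.00149). Fam60a in the Sin3a knockdown measured 15.6 ± 2.66 CPM and did not pass the test (log2 fold change 0.20 ± 0.22, adjusted p = 0.609). Sin3a in the Fam60a knockdown measured 217 ± 9.9 CPM, 75.6% of control (log2 fold change -0.40 ± 0.11, adjusted p = 0.0964). Without Sin3a knockdown replicate 3 that difference in Sin3a had an adjusted p of 0.00466, within a range of 4.19e-05 to 0.371 over its alternatives. The Fam60a call ended with no filter (0.0539), with a GC correction (0.095), with that correction and the replicate block (0.0677), and without any single library other than Sin3a knockdown replicate 3 (0.051 to 0.133).

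**Figure D1:**
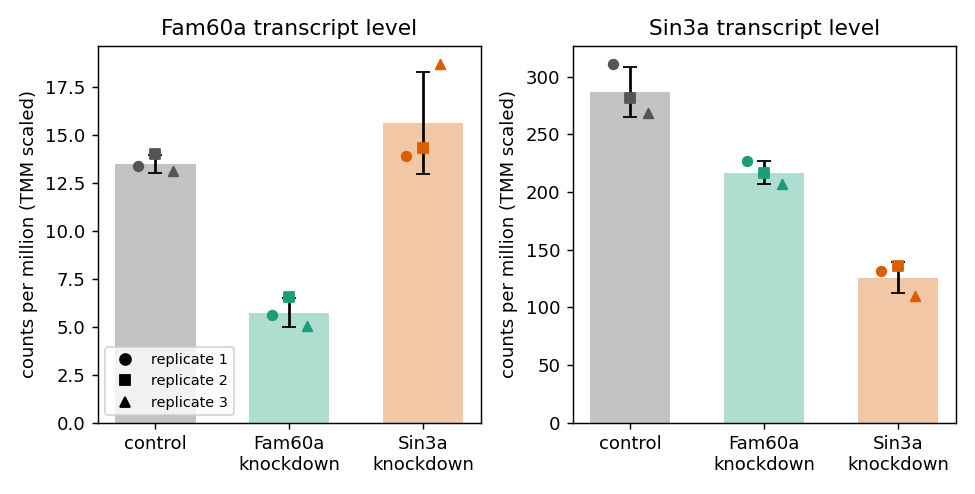
Transcript levels of Fam60a (left) and Sin3a (right) in CPM after TMM scaling, where bars give the mean of 3 libraries per group, error bars the SD, and symbols the single libraries by replicate number. Fam60a knockdown libraries lay between 5.06 and 6.54 for Fam60a against 13.1 to 14 in controls, and Sin3a knockdown libraries between 110 and 136 for Sin3a against 268 to 311.

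One library stood apart from the rest. Sin3a knockdown replicate 3 held 2607872 reads, against at least 5511453 in the other 8 libraries, and its mean correlation with its own group was 0.885, against 0.935 to 0.981 for the others. Genes with an exon GC content of at most 41.5% had a median log2 deviation of -1.22 from the other Sin3a knockdown libraries, and genes with at least 58% one of 0.754. Genes of the mitochondrial genome had 90 reads in it, against 6268 to 7118 in each other library. Pou5f1, a core pluripotency factor, measured 316 CPM in it and 131 and 152 CPM in the other Sin3a knockdown libraries, and Sin3b, a paralog of Sin3a, 247 against 116 and 117 CPM. Each count of genes is therefore given with and without this library.

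**Figure D2:**
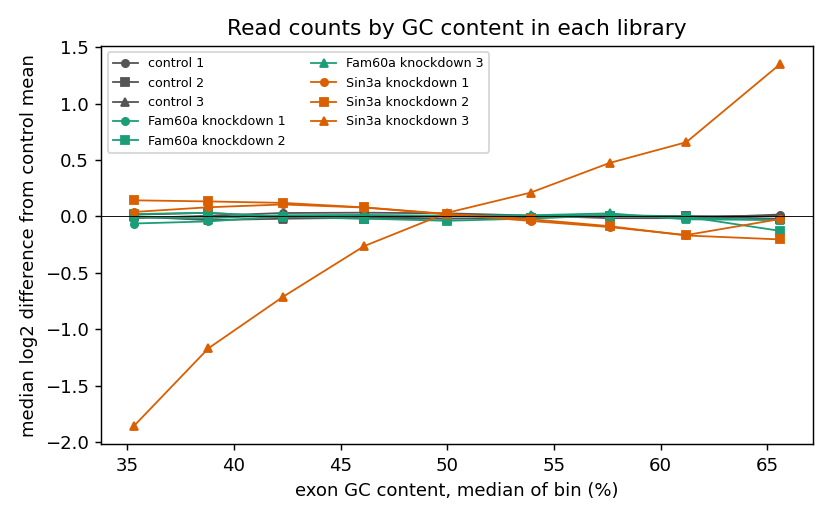
Median log2 difference of genes from the control mean (vertical axis) in bins of exon GC content in percent (horizontal axis), one line per library. Sin3a knockdown replicate 3 runs from -1.86 in the lowest bin to 1.35 in the highest, while the other 8 libraries stay between -0.205 and 0.142.

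The second comparison, of the Fam60a knockdown with the controls, asks which transcripts differ when this subunit of the complex is lowered. Off-target effects of the hairpins and binding of genes by the complex were not tested. Cyclin D1 (Ccnd1), which drives entry into S phase, fell from 154 ± 10 to 66.7 ± 11.3 CPM (SD, n = 3 each), a log2 fold change of -1.21 ± 0.14 (adjusted p = 0.00852). Itga4 and Itga1, integrin subunits that bind fibronectin and collagen respectively, rose from 1.34 ± 0.85 to 22.1 ± 7.04 CPM and from 1.95 ± 0.59 to 25.7 ± 10.4 CPM. Their log2 fold changes were 4.01 ± 0.62 and 3.70 ± 0.51. Lefty1 and Lefty2, secreted inhibitors of Nodal signalling, fell from 69.9 ± 4.74 to 14 ± 4.5 CPM and from 86.2 ± 16.8 to 26.5 ± 8.77 CPM. Prdm14, a transcriptional repressor that upholds naive pluripotency, fell from 72.2 ± 6.96 to 25.8 ± 8 CPM (log2 fold change -1.49 ± 0.28, adjusted p = 0.0291).

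Among the protein-coding genes with the largest rises were further receptors and enzymes. Ptafr, the receptor of platelet-activating factor, rose by 4.01 ± 0.72 on the log2 scale, the short-chain fatty acid receptor Ffar3 by 3.58 ± 0.48, and the glutamate receptor Grm6 by 3.40 ± 0.47. The lysyl oxidase Loxl4 rose by 3.13 ± 0.49 and the aldehyde oxidase Aox3 by 3.07 ± 0.51. Ly6c1, a surface antigen of blood and endothelial cells, rose from 0.203 ± 0.23 to 5.48 ± 2.13 CPM. On the other side, the atypical cadherin Fat2 had 159 reads over the 3 controls and 3 over the 3 knockdown libraries, a ratio of 55.6 with a 95% counting interval of 18.7 to 272. Tissue kallikrein Klk1 fell with a log2 fold change of -4.17 ± 0.40, the brain proteoglycan neurocan (Ncan) with -3.73 ± 0.50 and the lymphocyte receptor Cd6 with -3.63 ± 0.46. The neuronal calcium-binding protein calretinin (Calb2) fell with -3.51 ± 0.43 and the Ras activator Rasgrp1 with -3.20 ± 0.43. Foxr2, a forkhead factor, fell from 7.10 ± 0.77 to 0.505 ± 0.33 CPM.

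Targets of p53 formed the list with the smallest p in this comparison. Of 27 tested, 6 rose and 0 fell (6 and 0 adjusted over the list alone), 11 rose without Sin3a knockdown replicate 3, and the list stood higher than other genes (camera adjusted p = 2.42e-05, but adjusted p = 0.147 with an estimated correlation). Perp, a membrane protein of desmosomes and apoptosis, rose from 28 ± 4.02 to 96.4 ± 7.92 CPM and the BH3-only gene Pmaip1 (Noxa) from 37.2 ± 4.32 to 70.9 ± 5.77 CPM. The antiproliferative gene Btg2 rose from 61.2 ± 3.68 to 106 ± 5.11 CPM and the kinase gene Plk2 from 53.5 ± 10.1 to 108 ± 13.9 CPM. Without control replicate 1, 58 of the 59 named genes called in this comparison were no longer called, and only Klk1 stayed. Cdkn1a, which encodes the cell cycle inhibitor p21, did not pass (log2 fold change 0.39 ± 0.22, adjusted p = 0.48). Genes of primed pluripotency stood lower (camera adjusted p = 0.000673, but adjusted p = 0.147 with an estimated correlation). Of these 17 genes 3 fell and 0 rose, or 7 fell and 1 rose adjusted over the list alone. Crmp1, an axon guidance mediator, fell from 119 ± 6.5 to 44.1 ± 3.59 CPM. The zinc finger factor Zic2 fell from 37.6 ± 4.22 to 13.0 ± 1.9 CPM and the carbonic anhydrase Car14 from 4.66 ± 1.25 to 0.808 ± 0.45 CPM. In the neuroectoderm list, which stood lower (camera adjusted p = 0.0466, but adjusted p = 0.481 with an estimated correlation), 2 of 14 genes fell (2 adjusted over the list alone). They were the neuronal RNA-binding protein gene Elavl3 (47.6 ± 2.75 to 11.4 ± 3.2 CPM) and the neuronal tubulin Tubb3 (89.9 ± 10.4 to 33.4 ± 5.13 CPM). That list had an adjusted p of 0.0848 with the replicate block, in a range of 0.0162 to 0.481 over its alternatives. Its call also ended with no filter (0.213), with the GC correction (0.101), and without Fam60a knockdown replicate 1 (0.0971), Fam60a knockdown replicate 2 (0.121), Sin3a knockdown replicate 2 (0.0564), control replicate 1 (0.0551) or control replicate 3 (0.153).

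Genes of primitive endoderm, the extraembryonic lineage that embryonic stem cells can form, stood higher as a list (camera adjusted p = 0.000432, but adjusted p = 0.782 with an estimated correlation), with a median log2 fold change of 0.502 over 21 genes. Control replicate 3 stood apart for the whole list, with a median of 1 relative to the control mean, against -0.488 and -0.355 in the other controls, 0.542, 0.391 and 1.43 in the Fam60a knockdown and 0.718, 0.582 and 1.67 in the Sin3a knockdown (replicates 1 to 3). None of its members passed the edgeR test (0 adjusted over the list alone, 3 at an unadjusted p under 0.05). With the replicate block 5 rose, among them the lineage factor Gata6. It measured 85.0 ± 45.1 CPM in the controls and 192 ± 20.1 CPM in the knockdown. Its log2 fold change was 1.18 ± 0.30 (adjusted p = 0.0792, or 0.0361 with the block, range over alternatives 0.00828 to 0.262). In control replicate 3 this gene measured 137 CPM, against 57.0 and 61.0 CPM in the other controls. Trophectoderm genes also stood higher (camera adjusted p = 0.011, but adjusted p = 0.782 with an estimated correlation). Control replicate 3 stood apart here too, with a list median of 0.304 against -0.106 and -0.197 in the other controls and 0.35, 0.517 and 0.767 in the Fam60a knockdown, and the difference within the pair of replicates 3 was 0.201. Of 17 tested, Tead4, a Hippo pathway factor of that lineage, rose from 80.9 ± 8.74 to 125 ± 11.1 CPM, and 5 rose adjusted over the list alone. This call ended with fry (adjusted p = 0.266), without control replicate 1 (0.0551) and without control replicate 2 (0.0792).

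The other 25 of the 30 lists were not called here (camera adjusted p from 0.0624 to 0.996). In general pluripotency 1 of 21 genes fell (2 adjusted over the list alone), the repressor Tcf7l1 (140 ± 6.52 to 87.8 ± 6.1 CPM), and in naive pluripotency 1 of 25 (3 adjusted over the list alone), Prdm14. The factors Pou5f1, Sox2, Nanog, Klf4, Esrrb and Zfp42 had log2 fold changes between -0.34 and -0.04 and did not pass. Of 19 genes of primitive streak and mesendoderm 2 rose and 2 fell (6 and 2 adjusted over the list alone). Axin2, a feedback inhibitor of Wnt signalling, rose from 60 ± 4.08 to 108 ± 17.2 CPM and the homeobox gene Cdx4 from 0.705 ± 0.42 to 3.78 ± 0.73 CPM, and the members that fell were Lefty1 and Lefty2. The last pair also fell in the TGF-beta and BMP response list, where 1 of 24 genes rose and 2 fell (2 and 3 adjusted over the list alone). Tgfbr2, the type II TGF-beta receptor, rose from 22.1 ± 6.49 to 92.9 ± 13.1 CPM. Of 9 CDK inhibitors and RB family genes the inhibitor Cdkn2c rose, from 4.90 ± 1.47 to 15.8 ± 1.54 CPM (1 adjusted over the list alone). Of 32 G1/S and DNA replication genes Ccnd1 fell (1 adjusted over the list alone). Of 29 Polycomb subunits Bmi1 rose, from 33.6 ± 2.75 to 61.9 ± 6.98 CPM (1 rose and 1 fell adjusted over the list alone). Of 23 imprinted genes Usp29 fell (1 adjusted over the list alone). Of 29 germline and meiosis genes Tdrd12, of the piRNA pathway, fell from 45.8 ± 1.67 to 16.9 ± 3.98 CPM (2 rose and 5 fell adjusted over the list alone).

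No member passed the edgeR test in the lists of SIN3-HDAC complex subunits, smooth muscle, actin and SRF target genes, Hox cluster genes, two-cell-like state, G2/M and mitosis, and Myc and ribosome biogenesis. The same held for glycolysis and hypoxia response, cholesterol biosynthesis, oxidative phosphorylation, integrated stress response, interferon response, DNA methylation enzymes, fibroblast markers, immediate early and heat shock, replication-dependent histones and mitochondrially encoded genes. Adjusted over the list alone, 2 genes of cholesterol biosynthesis fell, and 1 fibroblast marker rose and 1 fell. Together with primitive endoderm these 17 lists held 305 tested entries, of which 27 had an unadjusted p under 0.05. Over all 14465 tested genes 2273 had such a p in edgeR, a larger share.

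In all, 215 genes rose and 208 fell against the controls, 346 of the 423 by at least 2-fold (edgeR adjusted p under 0.05). On its own 6 libraries this comparison had 1827 calls, while in the main fit the Sin3a knockdown libraries share in its estimate of the spread. The count was 887 with the replicate block (493 higher, 394 lower), 2495 without Sin3a knockdown replicate 3, and between 11 (without control replicate 1) and 312 without another single library. Of 59 named genes called here, between 7 (without Sin3a knockdown replicate 2) and 58 (without control replicate 1) were no longer called without 1 of those other 8 libraries, and Klk1 was the gene called in every such fit.

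The third comparison, of the Sin3a knockdown with the controls, asks which transcripts differ when the scaffold of the complex is lowered. Lefty1 and Lefty2 fell from 69.9 ± 4.74 to 1.93 ± 0.87 CPM and from 86.2 ± 16.8 to 1.49 ± 0.61 CPM (SD, n = 3 each). Their log2 fold changes were -5.27 ± 0.37 and -5.72 ± 0.37 (adjusted p = 0.00074 and 0.000642). Foxj1, the master factor of motile cilia, rose from 2.99 ± 0.79 to 44.6 ± 24.8 CPM (log2 fold change 3.88 ± 0.43), with 27.7 and 33.1 CPM in replicates 1 and 2 and 73.1 CPM in replicate 3. Itga4 rose from 1.34 ± 0.85 to 24.8 ± 14.1 CPM (log2 fold change 4.20 ± 0.63), with 33.2 and 32.5 CPM in replicates 1 and 2 and 8.53 CPM in replicate 3. The imprinted zinc finger gene Peg3 rose from 112 ± 14.8 to 278 ± 37.1 CPM, and Pax6, a factor of eye and neural development, fell from 15.8 ± 1.19 to 2.26 ± 0.58 CPM.

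Other genes with large rises were Ccdc81, a coiled-coil gene (0.494 ± 0.29 to 10.6 ± 0.81 CPM) and Grm6 (1.84 ± 0.91 to 23.2 ± 7.59 CPM). Rises were also called for the synaptic vesicle gene Svop (2.12 ± 0.72 to 22.9 ± 8.27 CPM), the sialyltransferase gene St8sia2 (0.292 ± 0.29 to 3.85 ± 1.23 CPM) and the cilia and flagella gene Cfap44 (0.921 ± 0.44 to 8.60 ± 3.1 CPM). Cyp26b1, which degrades retinoic acid, rose by 3.36 ± 0.80 on the log2 scale, with 12.0, 9.47 and 54.0 CPM in the 3 libraries. Fat2 had 0 reads over the 3 knockdown libraries and was at least 38.6-fold lower than in the controls. The protease gene Ctsw had 1 read against 122, a ratio of 88.9 with a 95% counting interval of 15.7 to 3540, and Car14 had 1 read against 93, a ratio of 67.8 with an interval of 11.9 to 2710. The photoreceptor cadherin Cdhr1 fell from 27.1 ± 2.16 to 0.705 ± 0.69 CPM, the adhesion receptor Adgrd1 from 47.8 ± 2.15 to 1.44 ± 1.26 CPM and the serine protease Tmprss13 from 13.9 ± 2.13 to 0.287 ± 0.28 CPM.

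Of 27 targets of p53, 11 rose and 1 fell (14 and 1 adjusted over the list alone), and the list stood higher (camera adjusted p = 1.96e-08, but adjusted p = 0.0799 with an estimated correlation). Btg2 rose from 61.2 ± 3.68 to 132 ± 10.2 CPM, Plk2 from 53.5 ± 10.1 to 166 ± 21.2 CPM and Ddit4l, an inhibitor of mTOR signalling, from 25.3 ± 3.29 to 67.4 ± 6.26 CPM. Gdf15, a stress-induced secreted factor, fell from 22.3 ± 3.34 to 7.22 ± 1.22 CPM, and Cdkn1a did not pass (log2 fold change 0.30 ± 0.23, adjusted p = 0.431). Genes of the two-cell-like state, a rare state of cultured stem cells with transcripts of the early embryo, stood lower (camera adjusted p = 0.0018, but adjusted p = 0.805 with an estimated correlation). Their median log2 fold change was -1.05 over 14 genes. Control replicate 3 stood apart for this list, with a median of 0.396 against -0.257 and -0.145 in the other controls, and the differences within pairs 1, 2 and 3 were -0.589, -0.918 and -1.26. None passed the edgeR test over all genes, 7 fell adjusted over the list alone and 8 had an unadjusted p under 0.05. The list call ended with the replicate block and without Sin3a knockdown replicate 3 (0.0518).

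Primitive endoderm genes stood higher as a list (camera adjusted p = 4.92e-05, but adjusted p = 0.805 with an estimated correlation), with a median log2 fold change of 1.00. Replicate 3 exceeded the mean of replicates 1 and 2 by a list median of 1.5 in the controls, 0.62 in the Fam60a knockdown and 0.844 in the Sin3a knockdown. Gata6 rose from 85.0 ± 45.1 to 208 ± 12.9 CPM and the other 20 members did not pass (1 rose adjusted over the list alone). With the replicate block 15 rose, and without Sin3a knockdown replicate 3 the list call ended (camera adjusted p = 0.0665) at a median of 0.52.

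The other 27 lists were not called here (camera adjusted p from 0.326 to 0.996). In primed pluripotency 2 of 17 genes rose and 3 fell (3 and 4 adjusted over the list alone). Zic2 fell from 37.6 ± 4.22 to 7.25 ± 1.14 CPM and Crmp1 from 119 ± 6.5 to 51.1 ± 9.89 CPM. Dnmt3b, a de novo DNA methyltransferase, rose from 245 ± 44.3 to 375 ± 50.2 CPM, and Sox11 rose to 39.3, 37.5 and 157 CPM in the 3 libraries from 17.9 ± 2.24 CPM. In naive pluripotency 2 of 25 rose and 4 fell (2 and 5 adjusted over the list alone). Falls included the factor Klf2 (144 ± 11.5 to 84.8 ± 11.7 CPM) and the signalling cofactor Tcl1 (119 ± 9.99 to 59.6 ± 19.1 CPM). In general pluripotency 2 of 21 fell (2 adjusted over the list alone), Tcf7l1 and the growth factor gene Fgf4 (203 ± 4.99 to 155 ± 11.9 CPM). Pou5f1, Sox2, Nanog, Klf4, Esrrb and Zfp42 had log2 fold changes between -0.27 and 0.54 and did not pass. Cdkn1c, which encodes the cell cycle inhibitor p57, measured 38.3 and 33.8 CPM in replicates 1 and 2 and 169 CPM in replicate 3, against 81.0 ± 6.95 CPM in the controls. Its log2 fold change was -0.04 ± 0.53 (adjusted p = 0.97), and without replicate 3 it was -1.16 (0.000553, in a range of 3.7e-06 to 1 over its alternatives).

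In neuroectoderm 1 of 14 genes rose and 3 fell (1 and 3 adjusted over the list alone), with falls of Elavl3 (47.6 ± 2.75 to 8.47 ± 0.90 CPM), Tubb3 (89.9 ± 10.4 to 29.0 ± 7.84 CPM) and Pax6. In primitive streak and mesendoderm 1 of 19 rose and 3 fell (2 and 4 adjusted over the list alone). Axin2 rose to 92.1 ± 2.47 CPM and the ligand gene Wnt3a fell from 3.65 ± 1.37 to 0.225 ± 0.20 CPM. The TGF-beta and BMP response list had 2 of 24 risen and 2 fallen (3 and 3 adjusted over the list alone), with Tgfbr2 at 52.1 ± 18.2 CPM. Of 13 interferon response genes 3 fell (3 adjusted over the list alone), among them the transcription factor Irf1 (62.4 ± 12.8 to 26.9 ± 2.93 CPM). Of 20 integrated stress response genes 2 fell (4 adjusted over the list alone), Nupr1 (33.0 ± 1.21 to 6.86 ± 1.38 CPM) and Chac1. Of 22 cholesterol biosynthesis genes 3 fell (3 adjusted over the list alone), among them the reductase Dhcr7 (98.7 ± 8.38 to 54.3 ± 3.02 CPM). In germline and meiosis 2 of 29 rose and 1 fell (2 and 1 adjusted over the list alone). The germ cell ADP/ATP carrier Slc25a31 rose from 10.2 ± 2.18 to 38.2 ± 3.28 CPM and the paralog of a general transcription factor subunit Taf7l from 9.62 ± 0.98 to 38.8 ± 5.13 CPM.

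Of 21 SIN3-HDAC complex subunits Ing2, a reader of methylated histone H3, rose (1 adjusted over the list alone), to 72.7, 65.4 and 148 CPM from 39.5 ± 4.04 CPM. The catalytic subunits Hdac1 and Hdac2 and the cofactor Tet1 did not pass in either knockdown. Among 23 imprinted genes 1 rose and 2 fell (1 and 2 adjusted over the list alone). Among 12 fibroblast markers 2 rose and 2 fell (3 and 4 adjusted over the list alone). Among 19 smooth muscle, actin and SRF target genes 2 rose and 1 fell (2 and 1 adjusted over the list alone). The surface glycoprotein Thy1 was among the fibroblast markers that fell, from 24.7 ± 3.42 to 6.87 ± 2.44 CPM. Cdkn2c rose among 9 CDK inhibitors and RB family genes (2 adjusted over the list alone) and Dnmt3b among 13 DNA methylation enzymes (1 adjusted over the list alone). Single genes passed over all genes and not adjusted over the list alone in G1/S and DNA replication (Ccnd1 fell to 105 ± 4.11 CPM), glycolysis and hypoxia response (Ddit4 rose), Polycomb subunits (Bcor fell) and immediate early and heat shock (Bag3 fell). None passed in trophectoderm, Hox cluster genes, G2/M and mitosis, Myc and ribosome biogenesis, oxidative phosphorylation, replication-dependent histones and mitochondrially encoded genes. With the two-cell-like list these 8 lists held 134 tested entries, of which 16 had an unadjusted p under 0.05. Over all 14465 tested genes 3741 had such a p in edgeR, a larger share.

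In all, 566 genes rose and 909 fell, 1103 of the 1475 by at least 2-fold (edgeR adjusted p under 0.05). The count was 2164 with the replicate block (916 higher, 1248 lower), 3606 without Sin3a knockdown replicate 3 (1619 higher, 1987 lower) and between 521 (without control replicate 2) and 1465 without another single library. On the 6 libraries of this comparison alone it was 739. Of 98 named genes called here, 45 stayed called without any single library, among them Lefty1, Lefty2, Foxj1, Itga4, Peg3, Pax6, Btg2, Plk2, Perp, Elavl3, Tubb3, Zic2 and Crmp1. Without control replicate 1 or control replicate 2, 47 of the 98 were no longer called in each case, and without Sin3a knockdown replicate 3, 0 were lost.

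**Figure D3:**
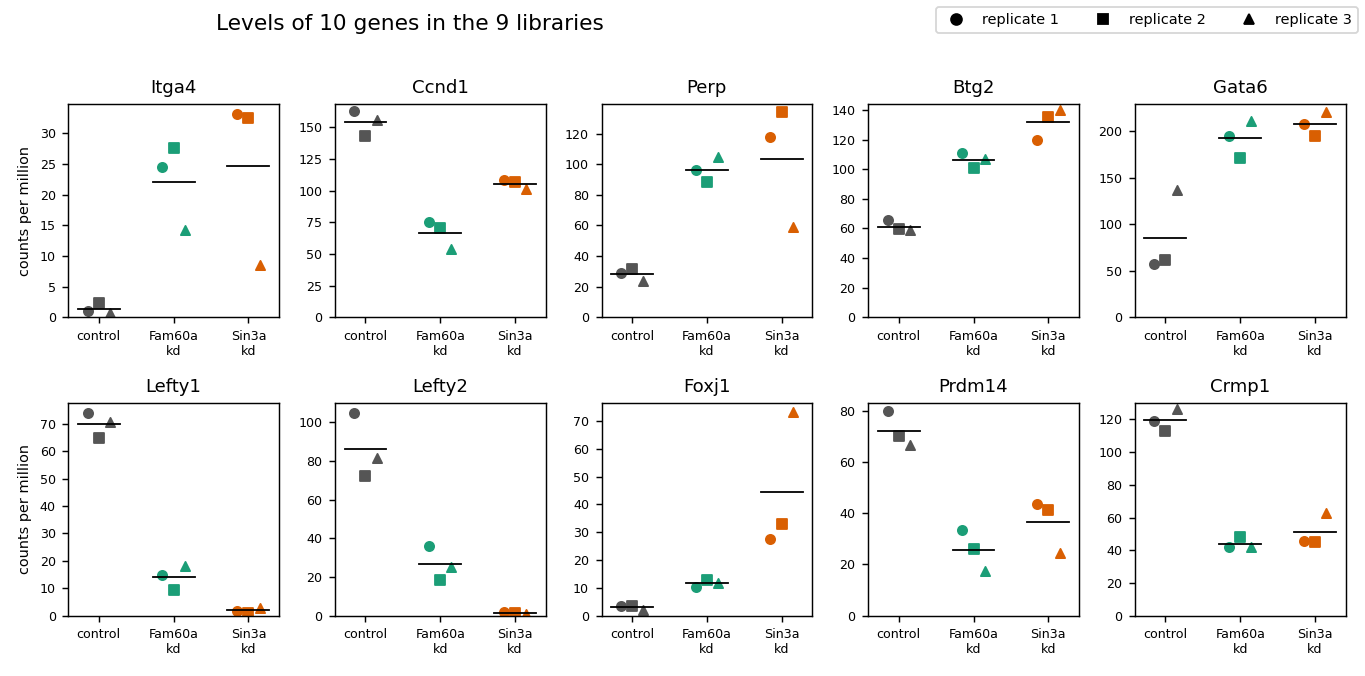
Levels of 10 named genes in CPM (vertical axes, each from 0) in the 3 control, 3 Fam60a knockdown (kd) and 3 Sin3a knockdown libraries, with a symbol per library and a line at each group mean. Lefty1 lay between the controls and the Sin3a knockdown in the Fam60a knockdown (means 69.9, 14 and 1.93), and the Sin3a knockdown libraries of Itga4, Perp and Foxj1 differ most between replicate 3 and the others.

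The fourth comparison set the changes of both knockdowns side by side, to ask how far they overlap. Of the genes called, 122 rose in both and 151 fell in both, which was 56.7% of the rises and 72.6% of the falls of the Fam60a knockdown, against 8.41 and 13.1 from lists of these sizes drawn independently. Itga4, Ptafr, Grm6, Ffar3 and the scaffold protein gene Gipc2 led the shared rises and Fat2, Cabp4, Tmprss13, Foxr2 and Calb2 the shared falls. Gipc2 measured 0.865 ± 0.13 CPM in the controls, 6.30 ± 0.96 CPM in the Fam60a knockdown and 6.47 ± 1.79 CPM in the Sin3a knockdown (SD, n = 3 each). The calls went in opposite directions for 4 genes, with the transcription factor gene Creb5, the D-lactate dehydrogenase Ldhd and the receptor Tnfrsf8 (CD30) higher in the Fam60a and lower in the Sin3a knockdown, and Gfod1 the reverse. Creb5 measured 3.60 ± 1.1, 14.1 ± 3.67 and 0.958 ± 0.30 CPM in controls, Fam60a knockdown and Sin3a knockdown, and Gfod1 54.9 ± 3.18, 21.2 ± 2.76 and 90.7 ± 13 CPM.

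Both comparisons used the same 3 controls, which by itself makes their fold changes covary. The covariance of the log2 fold changes across genes was 0.285 (Pearson r = 0.625 across genes, which are not independent replicates). In 20 simulations of unchanged groups with shared controls the highest covariance was 0.0661 and the highest r 0.511, the share of genes with the same sign averaged 66.4%, against 66.9% measured, and 0 genes were called in both by edgeR. These simulations left out the pairing by replicate number, and other splits of the libraries that part all numbers reached a covariance of 0.195. The r was between 0.335 and 0.596 over 6 combinations of single pairs that share no control library, but 3 controls cannot be divided into separate sets of at least 2, so the part of the overlap that comes from the shared controls was not separated. The overlap was 588 genes with the replicate block, 1314 without Sin3a knockdown replicate 3, and between 11 (without control replicate 1) and 156 without another single library. Among the 3 groups together, 1436 genes differed (edgeR joint test), 2124 with the replicate block and 4619 without Sin3a knockdown replicate 3. Without another single library the joint count was between 415 (without control replicate 1) and 1051.

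**Figure D4:**
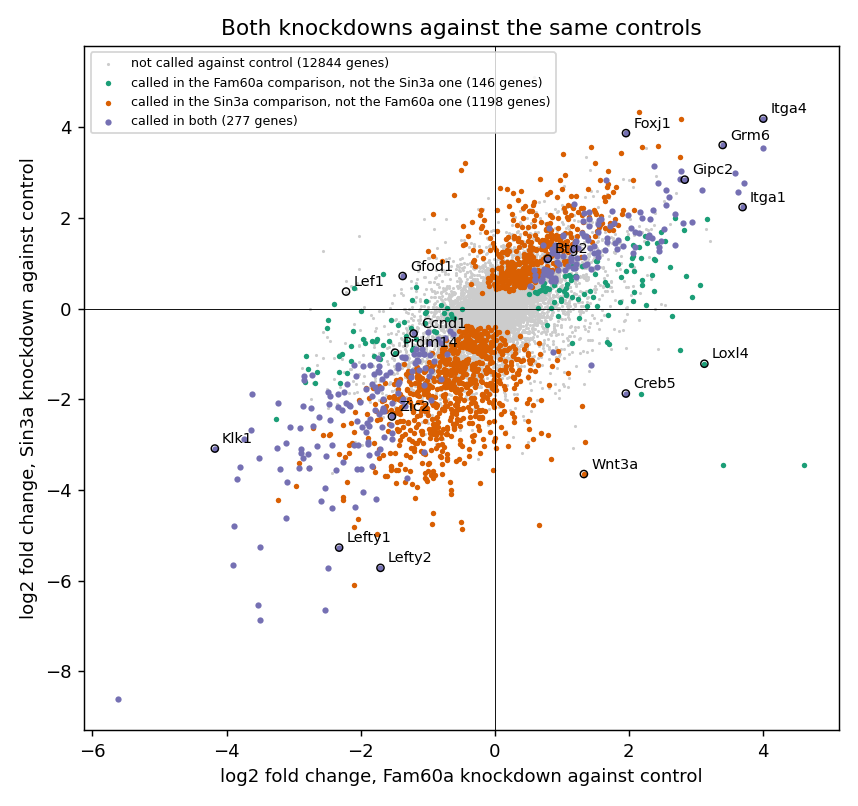
Log2 fold change of each of the 14465 tested genes in the Sin3a knockdown (vertical axis) against that in the Fam60a knockdown (horizontal axis), both against the same 3 controls, coloured by where the gene was called. The 277 genes called in both lie in the same direction except for 4, and 146 and 1198 genes were called in the Fam60a and the Sin3a comparison and not in the other.

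The last comparison tested the difference between the knockdowns directly, Fam60a knockdown against Sin3a knockdown, since a call in one and not in the other shows no difference. Lefty1 and Lefty2 were higher in the Fam60a knockdown by 2.95 ± 0.36 and 4.02 ± 0.36 on the log2 scale (adjusted p = 0.00716 and 0.00558, n = 3 each). The Wnt ligand gene Wnt3a measured 9.20 ± 4.03 CPM in the Fam60a and 0.225 ± 0.20 CPM in the Sin3a knockdown, and Osm, a cytokine related to leukaemia inhibitory factor, 8.26 ± 1.48 and 0.327 ± 0.31 CPM. Loxl4 (9.84 ± 3.26 against 0.378 ± 0.38 CPM), the innate immunity gene Pglyrp1 (6.02 ± 1.46 against 0.287 ± 0.28 CPM) and Creb5 were also higher, and Ly6c1, at 0 reads over the Sin3a knockdown, was at least 26.2-fold higher. Peg3 was lower in the Fam60a knockdown (114 ± 8.31 against 278 ± 37.1 CPM), as were the arginine methyltransferase gene Prmt8 (7.56 ± 2.55 against 45.0 ± 1.77 CPM) and the Wnt effector Lef1 (3.69 ± 2.68 against 22.4 ± 8.05 CPM). Further genes lower there were the factor Egr4 (0.511 ± 0.32 against 3.94 ± 1.49 CPM) and the cilia and flagella gene Cfap61 (0.729 ± 0.08 against 3.86 ± 1.1 CPM).

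Of 30 lists, 8 were called between the knockdowns, and 0 of them with an estimated correlation. Primitive streak and mesendoderm stood higher in the Fam60a knockdown (camera adjusted p = 0.000194, but adjusted p = 0.108 with an estimated correlation), with 4 of 19 genes higher and 0 lower (5 and 1 adjusted over the list alone). The members that were higher were Lefty1 and Lefty2, which inhibit Nodal, Wnt3a, and the homeobox gene Cdx1 (19.4 against 5.53 CPM). Two-cell-like genes stood higher (0.0126, but adjusted p = 0.492 with an estimated correlation), with none of 14 called and 1 higher adjusted over the list alone. This call ended with fry (adjusted p = 0.0842), without Fam60a knockdown replicate 3 (0.0537), and with the block and without Sin3a knockdown replicate 3 (0.124). Targets of p53 stood lower (0.0162, but adjusted p = 0.341 with an estimated correlation), with none of 27 called and 1 higher and 3 lower adjusted over the list alone. G1/S and DNA replication stood lower (0.0154, but adjusted p = 0.341 with an estimated correlation), with Ccnd1 lower among 32 (3 adjusted over the list alone). Myc and ribosome biogenesis also stood lower (0.0193, but adjusted p = 0.445 with an estimated correlation), with none of 25 called and 0 adjusted over the list alone. Sin3a knockdown replicate 3 stood apart for the Myc list, with a median of 0.403 against -0.0341 and 0.00815 in replicates 1 and 2, and without it the list median went from -0.273 to -0.094. The calls of the p53, G1/S and Myc lists each ended without Fam60a knockdown replicate 2 (0.0719, 0.0719 and 0.0856). The Myc call also ended with fry (adjusted p = 0.119).

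Primed pluripotency stood lower in the Fam60a knockdown (camera adjusted p = 0.0454, but adjusted p = 0.341 with an estimated correlation), with Lef1 lower among 17 genes (2 higher and 6 lower adjusted over the list alone). That call ended with the GC correction (0.064) and without Fam60a knockdown replicate 1 (0.0551), Fam60a knockdown replicate 2 (0.0856), control replicate 1 (0.0555) or control replicate 3 (0.0511). Fry ended the primed pluripotency call too (adjusted p = 0.0842). Smooth muscle, actin and SRF target genes stood lower (0.00797, but adjusted p = 0.597 with an estimated correlation), with none of 19 called and 3 lower adjusted over the list alone. Sin3a knockdown replicate 3 had a median of 0.913 for that list, against -0.0461 and 0.0492 in replicates 1 and 2. Without it the adjusted p was 0.626 and the list median turned from -0.42 to 0.0831. DNA methylation enzymes stood lower (0.0464, but adjusted p = 0.492 with an estimated correlation), with none of 13 called and 1 lower adjusted over the list alone. The same library had a median of 0.451 for these enzymes, against -0.016 and 0.129 in replicates 1 and 2. The p of that list was 0.0697 with the replicate block, 0.149 without Sin3a knockdown replicate 3, and between 0.0538 and 0.0719 without another single library except Sin3a knockdown replicates 1 and 2, without which it stayed called.

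The other 22 lists were not called between the knockdowns (camera adjusted p from 0.0719 to 0.923). Primitive endoderm was among them (0.148), with an adjusted p of 0.0477 with the replicate block in a range of 0.00853 to 0.953 over its alternatives. In the TGF-beta and BMP response 3 of 24 genes were higher in the Fam60a knockdown (3 adjusted over the list alone), among them Lefty1 and Lefty2. Pax6 was higher among 14 neuroectoderm genes (1 higher and 1 lower adjusted over the list alone) and Thy1 among 12 fibroblast markers (2 higher and 1 lower adjusted over the list alone). Peg3 was lower among 23 imprinted genes (1 adjusted over the list alone) and Slc25a31 lower among 29 germline and meiosis genes (3 adjusted over the list alone). No member was called in SIN3-HDAC complex subunits, general and naive pluripotency, primitive endoderm, trophectoderm, Hox cluster genes, CDK inhibitors and RB family, or G2/M and mitosis. Nor was any called in glycolysis and hypoxia response, cholesterol biosynthesis, oxidative phosphorylation, integrated stress response, interferon response, Polycomb subunits, immediate early and heat shock, replication-dependent histones or mitochondrially encoded genes. Adjusted over the list alone, 1 naive pluripotency gene was lower and 1 gene each of trophectoderm, Hox cluster and integrated stress response was higher. Together with the called lists that had none, the lists without a called member numbered 22 and held 421 tested entries, of which 66 had an unadjusted p under 0.05. Over all 14465 tested genes 2624 had such a p in edgeR, a larger share.

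In all, 316 genes were higher and 127 lower in the Fam60a than in the Sin3a knockdown, 358 of the 443 by at least 2-fold (edgeR adjusted p under 0.05). The count was 672 with the replicate block (468 higher, 204 lower), 2166 without Sin3a knockdown replicate 3, and between 48 (without Fam60a knockdown replicate 2) and 249 without another single library. On the 6 libraries of these groups alone edgeR called 0 genes, with 1760 at an unadjusted p under 0.05, and DESeq2 on all 9 libraries called 1267. Of 35 named genes called here, 9 stayed called without any single library, namely Creb5, Gfod1, Ldhd, Lefty1, Lefty2, Osm, Peg3, Prmt8 and Tnfrsf8.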

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

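The GC correction, its combination with the replicate block, and the block without Sin3a knockdown replicate 3 were chosen after seeing the data. Counts below are of genes for Fam60a knockdown against control, Sin3a knockdown against control, Fam60a against Sin3a knockdown, the joint test and the overlap, in that order. Of the called results, 0 named genes changed the sign of their fold change and 0 lists the direction of their test. Changes of sign among results that were not called were not counted. The median of the called smooth muscle, actin and SRF list between the knockdowns did change sign without Sin3a knockdown replicate 3. With the replicate block the Fam60a count, the count between knockdowns and the overlap were 887, 672 and 588, and with the GC correction 719, 822 and 464. With both they were 1686, 3297, 1555, 3561 and 1074, and with the block and without Sin3a knockdown replicate 3 they were 5842, 6975, 5321, 8797 and 3454. DESeq2 gave 1149, 2515, 1267, 2972 and 698. The 6 libraries of each contrast alone gave 1827, 739 and 0 genes, the last with 1760 at an unadjusted p under 0.05 in edgeR. An adjusted p under 0.01 gave 27, 392, 52, 308 and 21, by its construction.

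The fall of Fam60a was -1.24 with the GC correction, -1.231 with the replicate block and that correction and -1.189 with no filter, and none of these passed the threshold, nor did -1.231 at an adjusted p under 0.01. Without each library in turn it was between -1.335 and -1.147, and that of Sin3a between -1.214 and -1.088. The covariance of fold changes was 0.2347 with no filter and between 0.2526 and 0.3671 without single libraries. Called lists in the Fam60a comparison numbered 9 on its own 6 libraries, 9 with the block and without Sin3a knockdown replicate 3, and 3 at an adjusted p under 0.01, which left 2 between the knockdowns. With an estimated correlation 0 lists were called in each comparison, and fry called 5 in the Sin3a comparison. Where neither a construction nor the shared estimate of the spread is named, the cause was not tested. How much of a change the shared estimate accounts for was not measured.

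Without each library in turn the counts were 11 (without control replicate 1) to 2495, 521 (without control replicate 2) to 3606, 48 (without Fam60a knockdown replicate 2) to 2166, 415 to 4619 and 11 to 1314, each highest without Sin3a knockdown replicate 3. Called lists numbered 3 to 9, 2 to 4 and 3 to 12. Of 192 named calls, 149 ended under at least 1 alternative, 79 of them apart from left-out libraries and thresholds. The block ended 2, the GC correction 6, no filter 16, the own 6 libraries 74 and DESeq2 0. All 16 list calls ended with an estimated correlation, 8 with fry, which tests a list without comparing it with other genes, and 2 with the block. Those ended by fry were primitive endoderm in both knockdowns (fry adjusted p = 0.304 and 0.197) and trophectoderm in the Fam60a knockdown (0.266). Between the knockdowns they were primed pluripotency (0.0842), two-cell-like (0.0842), Myc (0.119), smooth muscle, actin and SRF (0.332) and DNA methylation enzymes (0.0993). What depth limits was not tested apart from the spread between replicates.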

Other observations

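All tests of explanations and of added lists in this part were chosen after the results were seen, while the other splits of the libraries were planned.

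Genes of the motile cilium, the beating organelle that Foxj1 controls, were not among the fixed lists. In a list that left out the genes that prompted it, 10 of 55 rose and 3 fell in the Sin3a knockdown (13 and 3 with the replicate block). Rsph1, of the radial spoke, rose from 12.2 ± 2.54 to 41.6 ± 1.21 CPM (SD, n = 3 each). Cfap52 rose from 3.38 ± 1.02 to 13.1 ± 3.51 CPM and Ccdc65, of the dynein regulatory complex, from 4.29 ± 1.11 to 14 ± 2.19 CPM. The dynein gene Dnah1 fell from 11.2 ± 2.35 to 1.92 ± 0.34 CPM and Hydin, of the central pair, from 60.9 ± 9.59 to 16.1 ± 1.18 CPM. The list stood higher than other genes (camera adjusted p = 0.0045, but adjusted p = 0.727 with an estimated correlation), which leaves open the hypothesis that ciliary genes rose as a group. In the Fam60a knockdown it stood lower (0.0166, but adjusted p = 0.727 with an estimated correlation), and it was lower there than in the Sin3a knockdown (2.63e-10, but adjusted p = 0.424 with an estimated correlation). Between the knockdowns 3 members were higher and 7 lower, or 3 and 13 with the block.

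A further pair of hypotheses rested on single genes. Since Lefty1 and Lefty2 are both targets and inhibitors of Nodal, a list of 17 other Nodal and Activin response genes was tested in the Sin3a knockdown, with an adjusted p of 0.889 (camera) and 0 members called by edgeR. With the replicate block 2 of them rose, Foxa2 and Chst15, and 2 fell, Fgf8 and Gdf3. Since Axin2 and Cdx4 rose in the Fam60a knockdown, 22 other Wnt targets were tested, with an adjusted p of 0.583 and 3 fallen, Fgf17, Notum and Sfrp5. That list left out Axin2, Cdx4 and also Lef1, which ran the other way (log2 fold change -2.22, adjusted p = 0.0632, or 0.0132 with the block, range over alternatives 1.06e-05 to 0.206). With the block Msx2 and Cdx2 rose as well, and the genes named here were chosen after their values were seen. Neither value decides whether those pathways changed.

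Sin3a knockdown replicate 3 stood apart, and 4 explanations were weighed. Lower depth was excluded, since the other libraries thinned to its total kept mean correlations of at least 0.934 with their groups, against its 0.885. A label from another group was excluded, since it held 110 CPM of Sin3a, against at least 207 CPM in control and Fam60a knockdown libraries. Its deviation from replicates 1 and 2 correlated with exon GC content at a Spearman rho of 0.586 across nuclear genes, which are not independent replicates, consistent with a GC bias of that library. The same bias did not account for its mitochondrial genes, whose median deviation was -4.44, below the lowest median of 10000 sets of nuclear genes matched on GC content (-3.54), and what lowered them stays open.

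Primitive endoderm genes stood higher as a list in both knockdowns (adjusted p = 0.782 and 0.805 with an estimated correlation), and without Sin3a knockdown replicate 3 the Sin3a call ended (0.0665, median 0.52). Replicate 3 exceeded replicates 1 and 2 by a list median of 1.5 in the controls, more than either knockdown's median (0.502 and 1.00). The list's median difference within same-numbered pairs was at least 0.373 in 6 of 6 pairs, which reuse the same controls. This argues against a difference tied to the replicate number as the whole cause. Differences between cultures that do not follow the number stay open, since the labels name no batches. With the replicate block and GC correction the list median was 0.963 in the Sin3a knockdown, which argues against a GC bias as the whole cause there. It was 0.658 in the Fam60a knockdown. That value is a weak test, since deviations of control and Fam60a knockdown libraries hardly followed GC content (Spearman rho from -0.101 to 0.0923). A larger share of primitive endoderm-like cells in the cultures could not be told apart from a change within cells, since 77.6% of the list's variance over the 9 libraries lay on 1 component and bulk RNA gives no counts of cells, so both stay open.

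Many genes changed the same way in both knockdowns. Sampling noise of the shared controls as the whole cause was excluded, since r across genes was at least 0.335 in 6 of 6 combinations of pairs that share no control library, where such noise cannot act. A property of the control line cannot be told apart from a shared effect of the knockdowns for the 256 genes called in both and not between them, because each comparison uses the same 3 control libraries. The other 17 shared genes were picked by their call between the knockdowns, which therefore decides nothing, and on the 6 libraries of those groups alone edgeR called 0 genes, with 1760 at an unadjusted p under 0.05 (DESeq2 on all 9 libraries called 1267).

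Other splits of the same libraries were tested as groups. For each pair of groups, with the remaining group kept in the model, 10 splits of 6 libraries are too few for a share under 0.05. The real splits called 423, 1475 and 443 genes (1 of 10 as many in each comparison). The highest other split called 0 genes by edgeR in each comparison, with 5 to 450, 41 to 1168 and 52 to 1312 genes at an unadjusted p under 0.05. The real splits had 2273, 3741 and 2624 such genes. For lists, the real splits called 5, 3 and 8 and 7, 9 and 4 of 10 splits called as many, with 11, 10 and 13 in the highest other and 9, 10 and 8 in the highest of the other splits that part all 3 pairs. The numbers of lists called thus did not stand out from other splits, and chance was not excluded for them. Of 280 splits of 9 libraries 100 were drawn. The 1436 genes of the joint test were the most over all drawn splits (1 of 100, highest other 131). Most of those splits mix replicate numbers, by which the libraries pair. Only 14 drawn splits part all numbers, the real one included, and the other 13 called 0 genes. The 14 drawn are too few for a share under 0.05. Further splits of this kind were among those not drawn, so chance was not excluded here with the pairing kept. The overlap of 273 (1 of 100, highest other 64) needs calls in both comparisons. Most other splits called 0 genes in the joint test, so the overlap decides nothing beyond that test. For the covariance of 0.285, chance was not excluded over all drawn splits (8 of 100, highest other 0.367). The other 7 keep libraries of the same number together, and the highest of the other 13 that part all numbers was 0.195.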
